A study of Mus musculus with 24 samples.

How the data were processed

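Total RNA of thymocytes from wild-type and Satb1 knockout mice aged 4 to 12 weeks was, per the labels, reverse transcribed with 5′ RACE and amplified with primers in the constant region of each receptor chain, and the amplicons were sequenced in paired reads on an Illumina HiSeq. The labels name the genotype as Satb1-/- while the series design names a conditional knockout. The authors trimmed reads with fastp, for which no version is stated; the aligner, the segment caller and the genome build are not given in the sources used here, and no molecular identifiers are named. The deposited values are in percent: each of the 24 tables, one per library, lists V segments against J segments and its cells sum to 100. Whether reads or distinct clonotypes were counted is not stated. No counts are given, so depth is not stated and no counting intervals were computed. In 23 of the 24 libraries all values were whole multiples of the smallest value above 0, within 0.01 of a multiple; in the Tcrd library of knockout replicate 2 this held for 50% of values. If the smallest value stands for a single assignment, depth could be inferred in those 23 libraries, but counts were not reconstructed.

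Groups were taken from the labels, with 3 libraries per genotype and chain, and each chain was compared alone. Segment positions were looked up by gene name in GENCODE M21 (GRCm38): 114 of 117 Tcra V segments and all segments of the other kinds were matched. V segments, J segments and V–J pairs with a mean share of at least 0.1% were tested with limma 3.58.1 in R 4.3.3 on log2(percent + pseudocount), the pseudocount being the smallest value above 0 of the finest library of that chain (0.0157 for Tcra, 0.00570 for Tcrb, 0.225 for Tcrg and 0.0128 for Tcrd). Adjusted p-values are Benjamini-Hochberg values within a chain and kind of feature, and calls were made at 0.05. A test on counts had been chosen before the data were examined; it was replaced by limma because the values are percentages. With 2 or 3 J segments in the Tcrg and Tcrd chains, limma shares little information between features. Lists by position (5′, middle and 3′ J segments; distal, middle and proximal V segments, J-proximal and distal V families; Tcrb V segments that are distal, central or near the D segments) were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry. The Tcra V segments with a position, delta V segments aside, were split by position into distal, middle and proximal classes of 37, 36 and 36 segments. The 5′ J list holds Traj42 and above, the 3′ list Traj21 and below. The 18 single values were compared with an exact two-sided permutation test over 20 arrangements, whose smallest p is 0.1. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

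The lists, the single values and the rule for named segments were fixed before the data were examined. For Tcra the rule took the 8 highest and 8 lowest called V and J segments with a mean of at least 0.5% in a genotype, any segment of at least 5%, and the 5 highest and 5 lowest called pairs of at least 0.1%. For Tcrb it took all J segments, V segments of at least 5% and called V segments, and for Tcrg and Tcrd segments of at least 1%. The V classes with delta V segments, the counts of pairs above 0 or making up 50% of a library, and the comparison of alpha and delta libraries were chosen after the data were seen.

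Alternatives planned beforehand were a smaller pseudocount, no filter, leaving out each library, treating replicates of equal number as a block, counting each V–J pair once, other bounds of the J lists, and other members of the J-proximal families. A larger pseudocount, centred log-ratios, a variance trend, a filter of 1%, summed near-identical V copies, the copies of Trav16, and limiting the single values to pairs at or above the coarsest library's smallest value were added after the data were seen. Whether equal replicate numbers pair the libraries was checked by correlating residuals of libraries with equal numbers, and pairing was taken where r exceeded 0.1 for all 3 numbers. In Tcrb V segments r was 0.767, 0.610 and 0.489, against at most -0.124 between other numbers. In Tcrb V–J pairs r was 0.375, 0.250 and 0.324, against at most -0.06 between other numbers. Blocked limma and camera values are therefore given beside the Tcrb results. For both kinds r was highest for number 1, the number whose Tcra libraries resembled each other. Tcrb J segments passed too, though r for numbers 2 (0.159) and 3 (0.293) lay below the highest between other numbers (0.294). The other chains did not pass. Tcra V–J pairs missed the bound with r of 0.0634, 0.135 and 0.170, against at most 0.0356 between other numbers, so pairing in Tcra stays open.

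The limma test was tested on simulated data built from the Tcra and Tcrb libraries, 20 runs each. Tcrg and Tcrd were not simulated, so the size of change that could be missed there is not known. Without rescaling to 100, it recovered 50.6% of 4-fold and 2.78% of 2-fold changes in Tcra J segments, 29.7% of 4-fold changes in Tcra V segments, 3.75% in Tcra pairs, and 86.3% of 2-fold changes in Tcrb V segments. With rescaling these were 33.3%, 0.556%, 20.9%, 6.50% and 86.3%. In Tcrb pairs limma recovered 48.9% of 2-fold changes without rescaling and 52.0% with it. In Tcrb J segments it recovered 100% of 4-fold changes, and after rescaling 72.0% of its calls were of segments that had not been changed before rescaling, since shares of a fixed total move together. For 2-fold changes this was 27.3%, and the largest rise seen in these segments was smaller, 1.26-fold. For 4-fold changes with rescaling it was 14.3% in Tcra J segments, 8.97% in Tcra V segments and 7.14% in Tcra pairs. For 2-fold changes without rescaling it was 37.5% and 60% of few calls in Tcra J and V segments.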

Results

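T cell receptor transcripts were profiled in thymocytes of wild-type mice and of Satb1 knockout mice on a C57BL/6 background. Satb1 is a nuclear protein that organises chromatin; the labels give the genotype as Satb1-/- and the series design as a conditional knockout. Each of the 4 receptor chains (Tcra, Tcrb, Tcrg and Tcrd) was amplified separately, with 3 wild-type and 3 knockout libraries per chain, 24 libraries in all. Each value is the percentage of a library's assignments that joined a given V segment to a given J segment. The tables hold no counts, and counts were not reconstructed from the percentages. If the smallest value above 0 stands for a single assignment, a coarser library is a shallower one. The resolution was read as the smallest value above 0. In the Tcra libraries it was 0.0158%, 0.0157% and 0.0241% in wild type and 0.0180%, 0.0593% and 0.117% in the knockout, so that 2 of the 3 knockout libraries were the coarsest. It lay between 0.00570% and 0.0133% in the Tcrb libraries, between 0.225% and 0.990% in the Tcrg libraries, and between 0.0128% and 0.0803% in the Tcrd libraries. Satb1 itself is not measured in these tables. All values below are means ± SD with n = 3 libraries per genotype. The limma and exact permutation p-values measure the spread between these libraries only, since the labels do not say that replicates are separate mice. The camera p-values compare the listed segments with the other segments of the same libraries at a preset correlation. They rest on the number and spread of segments and do not measure the spread between libraries alone. Positions are on chromosome 14 (Tcra, Tcrd), 6 (Tcrb) and 13 (Tcrg) of GRCm38.

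The first comparison asked whether loss of Satb1 altered which J segments the Tcra chain uses. In the knockout, Tcra transcripts were shifted to the 5′ end of the J array, the end nearest to the V segments, which is joined in the earliest rearrangements. The 5′ J segments (Traj42 and higher numbers) held 29.4% ± 1.73 of wild-type libraries and 75.6% ± 6.87 of knockout libraries. The 3′ J segments (Traj21 and lower numbers), which are reached by later rearrangements, held 31.7% ± 5.20 in wild type and 4.65% ± 3.20 in the knockout, where replicate 1 held 8.34% and the other 2 libraries had a mean of 2.80%. The Tcra library of knockout replicate 1 held 47 of the 186 3′ J pairs that wild-type replicate 1 shared with no other wild-type library. The mean J number was 30.5 ± 1.56 in wild type and 47.2 ± 2.28 in the knockout. For 5′ J share, 3′ J share and mean J number every knockout library lay outside the wild-type range, with p = 0.1 in an exact two-sided permutation test, the smallest that 3 against 3 libraries allow, and a Benjamini-Hochberg adjusted p of 0.18 over 18 single values. With each V–J pair counted once, the difference in 5′ J share was 29.7 instead of 46.2 percentage points and that in mean J number 11.1 instead of 16.6.

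Of 43 Tcra J segments tested with limma, 28 passed an adjusted p of 0.05: 8 rose and 20 fell in the knockout. All 8 that rose were 5′ J segments. TRAJ58 (54157280 to 54157342), the J segment closest to the V segments among those listed, rose from 2.58% ± 0.582 to 11.9% ± 1.50 (log2 fold change 2.22, adjusted p = 0.00743). TRAJ57 rose from 2.89% ± 0.256 to 11.7% ± 1.41, TRAJ56 from 3.62% ± 0.233 to 12.1% ± 1.44 and TRAJ53 from 1.88% ± 0.335 to 7.07% ± 1.70. TRAJ52, TRAJ50, TRAJ49 and TRAJ48 rose 2.96-fold, 3.33-fold, 1.78-fold and 2.18-fold. Among those that fell, TRAJ6 (54212688 to 54212749) went from 2.70% ± 0.905 to 0.241% ± 0.417 and TRAJ16 from 1.74% ± 0.318 to 0.108% ± 0.188. The knockout shares of TRAJ6, TRAJ16 and TRAJ2 came from replicate 1 alone, and the other 2 knockout libraries listed them at 0. TRAJ2, TRAJ17, TRAJ4, TRAJ13, TRAJ11 and TRAJ18 fell to shares between 0.102% and 0.323%. Without knockout replicate 1 the knockout mean was 0.0890% for TRAJ17, 0.178% for TRAJ4, 0.0593% for TRAJ13 and 0.0297% for both TRAJ11 and TRAJ18. TRAJ31, in the middle of the array, fell from 5.07% ± 0.247 to 1.37% ± 1.05, a knockout mean that was 0.766% without replicate 1. Of the 13 5′ J segments 8 rose, 0 fell and 5 were not called, and adjusted over the list alone 8 were called (camera adjusted p = 4.54e-13). Of the 14 3′ J segments 0 rose, 13 fell and 1 was not called, and adjusted over the list alone 13 were called (camera adjusted p = 0.000610). Of the 16 middle J segments 0 rose, 7 fell and 9 were not called, with 7 called adjusted over the list alone (camera adjusted p = 0.0523, but 0.0398 without wild-type replicate 1 and 0.0359 without knockout replicate 2). The 5′ call held with an estimated correlation (adjusted p = 0.00225 with an estimated correlation), while the 3′ call was lost (adjusted p = 0.221 with an estimated correlation). Of the 10 splits of the 6 libraries into 3 and 3, the real one included, 5 called as many J lists with camera. The count of 28 dropped to 2, 0 and 5 without wild-type replicate 1, 2 or 3, and none of those called was lower in the knockout. It was 12 without knockout replicate 2 (7 higher, 5 lower) and 16 with a smaller pseudocount (7 higher, 9 lower). After centring each library's log values, which moved the median of all J segments from -1.54 to -0.08, all 13 5′ J segments lay above 0 and all 14 3′ J segments below 0, but the middle J segments split into 7 above and 9 below. Centring left 21 J segments called, 12 higher and 9 lower in the knockout, and of the middle J segments 1 rose and 0 fell.

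**Figure D1:**
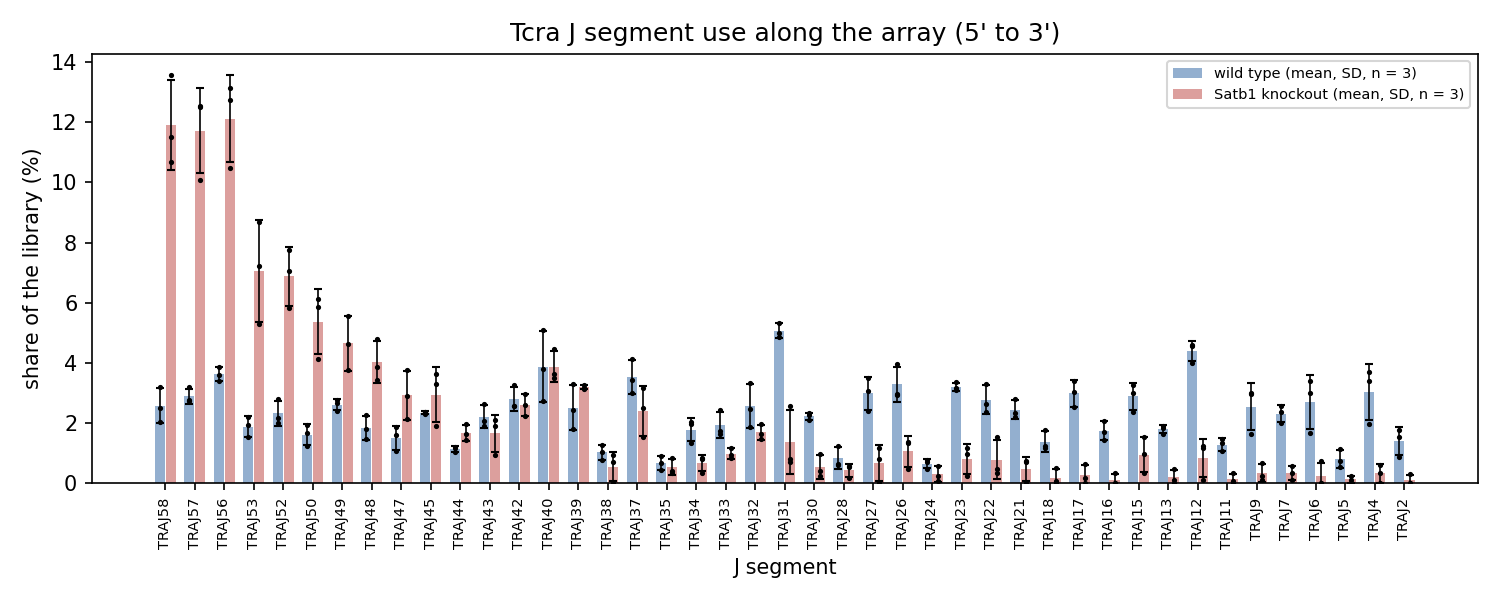
Share of each Tcra J segment (vertical axis, percent of the library) in array order from 5′ to 3′ (horizontal axis), in wild type and Satb1 knockout. Bars are means of 3 libraries, error bars are SD and dots are libraries. TRAJ58, TRAJ57 and TRAJ56 each held under 4% in wild type and 11.7% to 12.1% in the knockout.

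The same libraries were compared for V segment use in the Tcra chain. In the knockout 3 V segments near the J array rose: TRDV2-2 and TRDV1, which are delta V segments, and TRAV21/DV12, which serves both chains. TRDV2-2 (53960944 to 53961602) rose from 0.502% ± 0.0599 to 7.04% ± 2.12 (log2 fold change 3.74, adjusted p = 0.00758). TRAV21/DV12 (53875984 to 53876752) rose from 1.94% ± 0.374 to 11.4% ± 3.68 (log2 fold change 2.51, adjusted p = 0.0412), and TRDV1 (53881612 to 53882217) from 1.01% ± 0.269 to 7.17% ± 3.18 (log2 fold change 2.74, adjusted p = 0.0412). Together the delta V segments joined to Traj segments held 1.71% ± 0.322 in wild type and 14.8% ± 5.05 in the knockout.

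Of 84 Tcra V segments tested with limma, 4 passed: the 3 named above rose, and TRAV3-1 fell from 0.217% ± 0.119 to 0.0120% ± 0.0208 (adjusted p = 0.0456), a knockout share that came from replicate 1 alone. TRAV3-1 lies outside the rule for named segments and was chosen after its values were seen. TRAV17 (1.78% ± 0.0827 in wild type, 3.20% ± 0.638 in the knockout), TRAV19 (0.758% ± 0.179 and 2.65% ± 1.51) and TRDV2-1 (0.194% ± 0.117 and 0.568% ± 0.322), also near the J array, were not called and were chosen after their values were seen. TRDV4 and TRDV5, which lie nearer still, fell under the filter on low shares and were not tested. The abundant segments TRAV7D-5 (7.43% ± 1.42 in wild type, 10.1% ± 3.21 in the knockout) and TRAV4-4-DV10 (4.01% ± 1.20 and 6.67% ± 2.81) were not called. TRAV1, the V segment farthest from the J array and the one used by mucosal-associated invariant T cells, held 1.01% ± 0.421 and 0.0782% ± 0.135 with the knockout share from replicate 1 alone, and was not called (adjusted p = 0.0521). The J-proximal families (Trav17, Trav19 and Trav21, with Trav16 not tested) held 4.48% ± 0.556 of wild-type and 17.2% ± 4.28 of knockout libraries (exact permutation p = 0.1, adjusted 0.18). Their pairs with 5′ J segments held 3.14% ± 0.0800 and 13.8% ± 3.78 (exact permutation p = 0.1, adjusted 0.18). With each V–J pair counted once these differences were 5.36 instead of 12.8 percentage points and 4.13 instead of 10.7. Of the 3 J-proximal segments tested 1 rose, 0 fell and 2 were not called, with 1 called adjusted over the list alone (camera adjusted p = 0.000647, and adjusted p = 0.0769 with an estimated correlation). In the distal V class, farthest from the J segments, 0 rose, 1 fell and 25 were not called, with 5 called adjusted over the list alone (camera adjusted p = 0.0124, but 0.0554 without knockout replicate 3, and adjusted p = 0.139 with an estimated correlation). In the proximal V class 1 rose, 0 fell and 32 were not called, with 1 adjusted over the list alone. Camera placed that list up (adjusted p = 0.0125, and adjusted p = 0.139 with an estimated correlation) although its median and mean log2 fold changes were -0.19 and -0.22, with 14 segments above 0 and 19 below. After centring the median of this class was 0.74, with 27 above 0 and 6 below. The middle V class (0 rose, 0 fell, 22 not called, 0 adjusted over the list alone, camera adjusted p = 0.0763, but 0.0449 without wild-type replicate 3 and 0.0362 without knockout replicate 3) and the distal families Trav1 and Trav2 (0 rose, 0 fell, 2 not called, 1 adjusted over the list alone, camera adjusted p = 0.183) were not called. The count of 4 dropped to 0 without wild-type replicate 1, 2 or 3, to 2 without knockout replicate 2 and to 1 with a smaller pseudocount. Under several alternatives most calls were lower in the knockout: 3 rose and 10 fell without knockout replicate 1, 3 rose and 12 fell without knockout replicate 3 or with replicates of equal number as a block, 4 rose and 14 fell with a larger pseudocount, and 3 rose and 6 fell of 48 with near-identical copies of a V segment summed, since reads of such copies are hard to tell apart.

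**Figure D2:**
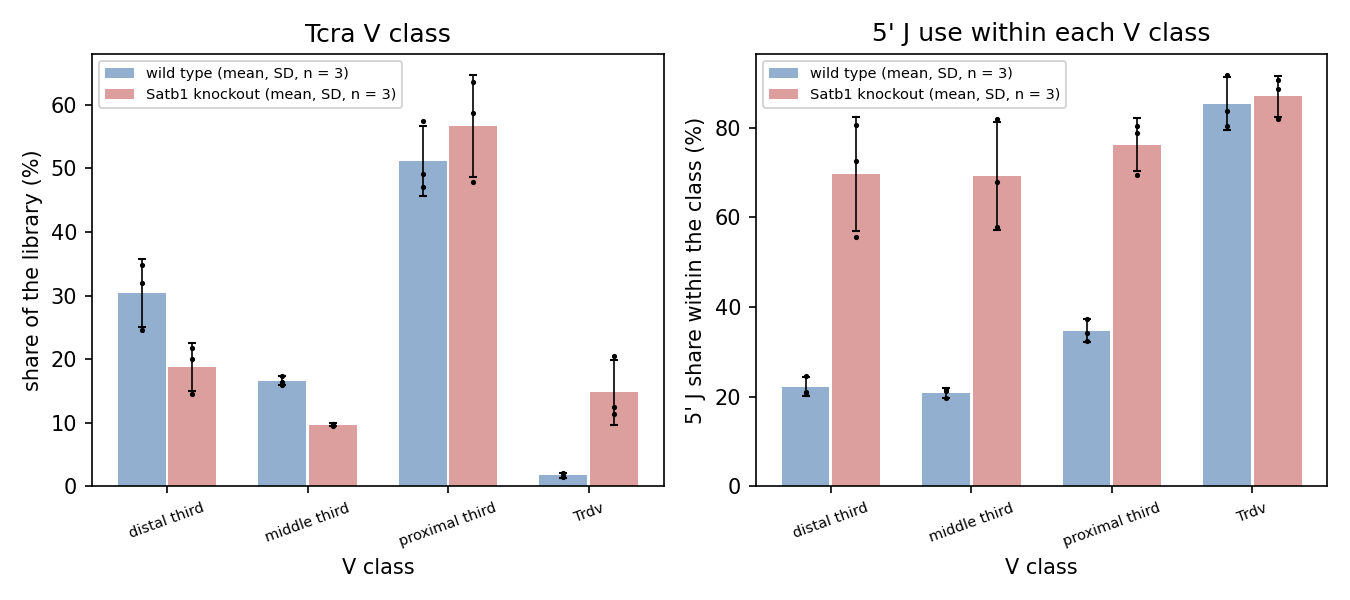
Left, share of the Tcra library (percent) held by each class of V segment; right, share of 5′ J segments (percent) within each class, in wild type and Satb1 knockout. Bars are means of 3 libraries, error bars are SD and dots are libraries; the 5′ J share within the distal class was 22.2% in wild type and 69.6% in the knockout.

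The V–J pairs of the Tcra chain were compared next, without a test of the called pairs by V and J class. Of 202 pairs tested with limma, 72 were called: 46 rose and 26 fell. Without a filter on low shares the balance turned, with 41 higher and 99 lower in the knockout among 140 called of 3123 pairs. Knockout replicates 2 and 3 list no value above 0 under 0.0593% and 0.117%. Lower calls among rare pairs thus cannot be told apart from coarser resolution. With the filter and the larger pseudocount, 79 pairs were called, 56 higher and 23 lower. TRDV2-2 with TRAJ50 rose from 0.00802% ± 0.0139 to 0.702% ± 0.267 (adjusted p = 0.00506), TRAV21/DV12 with TRAJ53 from 0.0241% ± 0.0417 to 0.899% ± 0.361 (adjusted p = 0.00644) and TRAV21/DV12 with TRAJ49 from 0.0369% ± 0.0510 to 0.670% ± 0.305 (adjusted p = 0.0165). The wild-type shares of TRDV2-2 with TRAJ50 and of TRAV21/DV12 with TRAJ53 each came from a single library. TRDV2-2 with TRAJ53 (0.387% ± 0.191) and with TRAJ48 (0.266% ± 0.0514) rose from pairs listed at 0 in all 3 wild-type libraries. TRAV7-4 with TRAJ27 held 0.204% ± 0.0818 in wild type and was listed at 0 in all 3 knockout libraries. TRAV12-2 with TRAJ31, TRAV7D-5 with TRAJ26, TRAV7D-5 with TRAJ6 and TRAV3D-3 with TRAJ12 fell from between 0.233% and 0.313% to between 0.00601% and 0.0241%, and these knockout shares came from replicate 1 alone, the other 2 libraries listing the pairs at 0. The pair of Trav11 with Traj18, the invariant receptor of natural killer T cells, held 0.0818% ± 0.0692 in wild type and 0.0241% ± 0.0417 in the knockout, where it was listed above 0 in replicate 1 alone (exact permutation p = 0.3, adjusted 0.45). That wild-type mean lies below the smallest value above 0 of knockout replicate 3 (0.117%). The pair of Trav1 with Traj33, that of mucosal-associated invariant T cells, held 0.0105% ± 0.00912 in wild type and was listed at 0 in all 3 knockout libraries (exact permutation p = 0.4, adjusted 0.554). The wild-type mean of this pair lies below the smallest value above 0 of every knockout library, so these listings at 0 cannot show a loss. The count of 72 dropped to 5 with a smaller pseudocount, to 12, 7 and 19 without wild-type replicate 1, 2 or 3, to 11 without knockout replicate 2, and to 36 after centring, where 25.0% of calls were higher in the knockout instead of 63.9%.

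The spread of Tcra transcripts over V–J pairs was lower in the knockout libraries as listed. Pair entropy was 10.3 ± 0.137 bits in wild type and 8.50 ± 0.697 bits in the knockout (exact permutation p = 0.1, adjusted 0.18). Pairs above 0 numbered 1978, 1969 and 1573 in wild type and 1380, 555 and 374 in the knockout, and 334 ± 24.7 against 87.0 ± 35.5 pairs made up 50% of a library. These values depended on which pairs were kept. Over pairs at or above the smallest value of the coarsest library, the difference in entropy was -0.0158 bits instead of -1.79, and the difference in pairs above 0 was 71.7 instead of -1070, and that in pairs making up 50% of a library was -20.3 instead of -247. This cut removes the rare pairs of the finer libraries, which are part of the spread being measured. It therefore cannot tell lower diversity apart from coarser resolution. Resolution alone did not order the libraries: knockout replicate 1 was finer than wild-type replicate 3, yet had lower entropy (9.29 against 10.1 bits) and fewer pairs above 0.

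For the Tcrb chain the question was again which segments were used. Knockout libraries held less of the J2 cluster, the J segments next to the second constant region, and more of the J1 cluster. The J2 cluster held 68.1% ± 0.996 in wild type and 61.7% ± 2.54 in the knockout, lower in every knockout library (exact permutation p = 0.1, adjusted 0.18). Of 11 J segments tested with limma, 6 were called: TRBJ1-2 (from 5.41% ± 0.629 to 6.58% ± 0.502), TRBJ1-3 (5.15% ± 0.432 to 6.30% ± 0.504), TRBJ1-4 (8.08% ± 0.156 to 10.2% ± 1.26) and TRBJ1-5 (2.86% ± 0.313 to 3.43% ± 0.222) rose, while TRBJ2-3 (11.5% ± 0.0641 to 10.0% ± 0.348) and TRBJ2-5 (12.2% ± 0.940 to 10.5% ± 0.583) fell, with adjusted p between 0.0314 and 0.0365. TRBJ1-1 (10.4% and 11.8%), TRBJ2-1 (11.9% and 10.7%), TRBJ2-2 (6.21% and 6.34%), TRBJ2-4 (10.4% and 9.70%) and TRBJ2-7 (16.0% and 14.5%) were not called. With replicates of equal number treated as a block, 7 J segments were called, with TRBJ1-1 added. The count of 6 dropped to 0 without wild-type replicate 2 or knockout replicate 1, to 2 without wild-type replicate 3, and to 4 without wild-type replicate 1 or knockout replicate 2.

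**Figure D3:**
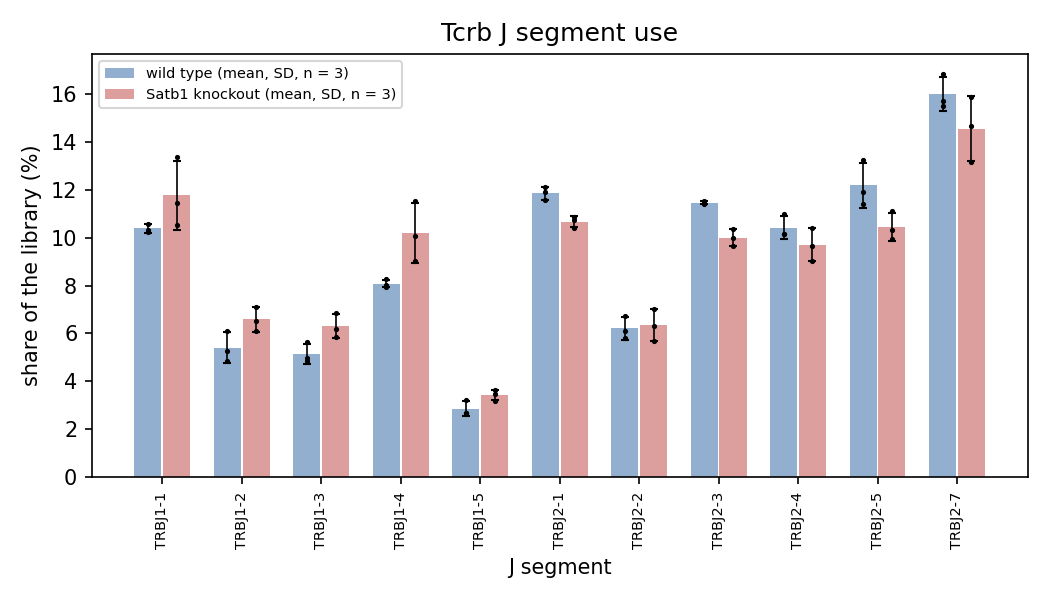
Share of each Tcrb J segment (vertical axis, percent of the library; horizontal axis, J segments of the J1 and J2 clusters) in wild type and Satb1 knockout. Bars are means of 3 libraries, error bars are SD and dots are libraries. TRBJ1-4 rose from 8.08% to 10.2%.

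No Tcrb V segment was called by limma among 22 tested (3 at an unadjusted p under 0.05). The segments of at least 5% in either genotype were TRBV13-2 (9.39% ± 0.472 in wild type, 8.57% ± 1.11 in the knockout), TRBV12-1 (9.05% ± 0.261 and 9.16% ± 1.34), TRBV5 (8.60% ± 2.35 and 8.81% ± 2.66), TRBV13-1 (8.16% ± 0.806 and 6.62% ± 1.35), TRBV3 (7.22% ± 0.964 and 7.40% ± 2.37), TRBV16 (6.42% ± 0.656 and 6.02% ± 0.856), TRBV15 (5.60% ± 0.221 and 3.90% ± 0.328), TRBV17 (5.37% ± 1.01 and 5.99% ± 0.925), TRBV29 (4.46% ± 0.461 and 5.34% ± 0.402) and TRBV2 (4.09% ± 0.194 and 6.06% ± 1.16). With replicates of equal number treated as a block, 3 V segments were called: TRBV2 and TRBV20 (3.03% ± 0.293 and 4.71% ± 0.488) were higher and TRBV15 lower in the knockout. TRBV20 was chosen after its values were seen. Without knockout replicate 3, 1 V segment (TRBV2) was called. TRBV31, which lies downstream of the constant regions and joins by inversion, held 3.89% ± 1.31 in wild type and 3.28% ± 1.04 in the knockout (exact permutation p = 0.5, adjusted 0.6). Within each replicate number the knockout share was lower: 5.41% against 4.48%, 3.15% against 2.69% and 3.12% against 2.68%, wild type first. Without wild-type replicate 1 the difference was 0.143 percentage points instead of -0.613. Leaving out that library alone keeps knockout replicate 1, the highest knockout library, and so breaks their pair. Of the lists by position, the distal V segments (0 rose, 0 fell, 5 not called, camera adjusted p = 0.592), the central V segments (0 rose, 0 fell, 11 not called, camera adjusted p = 0.543) and those near the D segments (0 rose, 0 fell, 5 not called, camera adjusted p = 0.543) showed no call, with 0, 2 and 0 called adjusted over the list alone. With the block the camera adjusted p of these lists was 0.639, 0.628 and 0.628. For the distal V segments the median log2 fold change (-0.00242) and the mean (0.0639) differed in sign. No V–J pair was called by limma among 209 tested (25 at an unadjusted p under 0.05), and 3 were called without wild-type replicate 3. With replicates of equal number as a block, 0 pairs were called and 35 had an unadjusted p under 0.05. Pair entropy was 7.47 ± 0.0645 bits in wild type and 7.52 ± 0.0495 bits in the knockout (exact permutation p = 0.6, adjusted 0.675).

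In the Tcrg chain the knockout libraries were compared with wild type for the use of the 7 V and 3 J segments. TRGV2 was the main segment in both genotypes, with 65.6% ± 1.27 in wild type and 60.9% ± 1.09 in the knockout. It was lower in every knockout library (62.0%, 59.9% and 60.7%) than in any wild-type library (64.2%, 66.4% and 66.3%). Chance gives no overlap in 10% of splits. TRGV4 held 14.8% ± 2.59 and 19.8% ± 2.67, TRGV1 held 16.0% ± 1.59 and 16.5% ± 5.37, TRGV6 held 0.714% ± 0.646 and 1.60% ± 0.881, and TRGV7 held 1.22% ± 1.06 and 0.490% ± 0.664. TRGJ2 held 58.6% ± 7.26 and 59.8% ± 3.37, TRGJ1 held 27.3% ± 10.2 and 26.6% ± 1.96, and TRGJ4 held 14.1% ± 4.26 and 13.6% ± 2.78. Limma called 0 of 7 V segments, 0 of 3 J segments and 0 of 16 V–J pairs, and each had 0 at an unadjusted p under 0.05. With a filter of 1%, 0 of 4 V segments were called and 1 had an unadjusted limma p under 0.05. V segments of the J1 cluster (Trgv4, Trgv5, Trgv6 and Trgv7) held 17.7% ± 2.51 and 22.2% ± 4.06 (exact permutation p = 0.3, adjusted 0.45). The fetal-type segments Trgv5 and Trgv6, used by the first gamma delta T cells of the fetus, held 1.70% ± 1.11 and 1.90% ± 1.01 (exact permutation p = 1, adjusted 1), a difference of 0.194 percentage points that was -0.0296 or -0.216 without wild-type replicate 1 or 2 and -0.0933 or -0.103 without knockout replicate 1 or 3. Pair entropy was 2.16 ± 0.309 and 2.21 ± 0.274 bits (exact permutation p = 0.8, adjusted 0.847), and the difference of 0.0506 bits was -0.113 without wild-type replicate 1 and -0.0620 without knockout replicate 3. With a smallest value of up to 0.990%, rare segments were not resolved.

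In the Tcrd chain the same question was asked for 15 V and 2 J segments. TRDV2-2 was the main segment and held 53.9% ± 3.54 in wild type and 65.6% ± 7.30 in the knockout. TRDV5, which lies downstream of the constant region, held 10.2% ± 3.08 and 10.1% ± 3.62, TRDV1 held 9.84% ± 1.93 and 7.44% ± 1.81, and TRAV15-2-DV6-2 held 7.54% ± 0.348 and 3.48% ± 2.47. TRAV21/DV12 held 6.46% ± 0.513 and 4.45% ± 1.92, TRAV13-4-DV7 held 5.20% ± 2.06 and 4.99% ± 2.42, and TRAV15-1-DV6-1 held 4.18% ± 2.52 and 2.25% ± 0.873. Limma called 0 of 13 V segments, 0 of 2 J segments and 0 of 18 V–J pairs, and each had 0 at an unadjusted p under 0.05. V segments shared with the alpha chain held 25.9% ± 2.71 in wild type and 16.3% ± 4.36 in the knockout, Trdv4, a fetal-type segment, 0.102% ± 0.0885 and 0.367% ± 0.156, and pair entropy was 2.39 ± 0.109 and 2.00 ± 0.189 bits. For these 3 measures all knockout libraries lay outside the wild-type range, at the smallest exact permutation p of 0.1 (adjusted 0.18), where chance gives no overlap in 10% of splits. They are not independent, since shares sum to 100 and TRDV2-2 was itself higher in every knockout library. Trdv4 lay near the resolution, with 0.160%, 0.146% and 0% in wild type and 0.320%, 0.541% and 0.241% in the knockout. The smallest value above 0 was up to 0.0803% in this chain. TRDJ1 held 98.2% ± 0.523 and 96.7% ± 2.50 (exact permutation p = 0.5, adjusted 0.6), and TRDJ2 held 1.76% ± 0.523 and 3.26% ± 2.50. The higher knockout mean of TRDJ2 came from replicate 1 (6.12%), while replicates 2 and 3 held 1.56% and 2.09%.

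**Figure D4:**
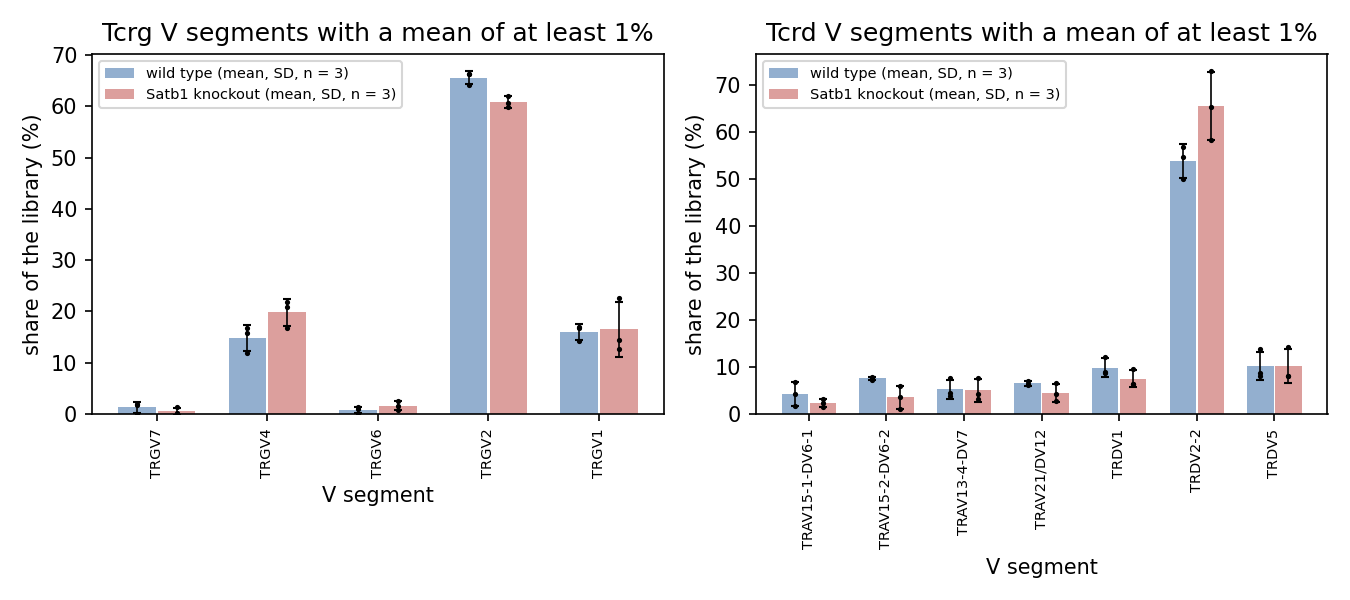
Share of V segments (vertical axes, percent of the library) with a mean of at least 1% in either genotype, for Tcrg (left) and Tcrd (right), in wild type and Satb1 knockout. Bars are means of 3 libraries, error bars are SD and dots are libraries; TRGV2 held 65.6% and 60.9%, and TRDV2-2 of Tcrd 53.9% and 65.6%.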

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

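The tests of explanations in this part were chosen after the results were seen; the counts over other splits of the samples were set beforehand, but what they would show was written down only after they were seen. The V segments that serve both the alpha and the delta chain were compared between the 2 chains, because effects of the knockout differed between them. Of 9 shared V segments tested for the difference of effects with limma, 3 passed: the knockout effect in Tcra exceeded that in Tcrd by 3.45 on the log2 scale for TRDV2-2 (adjusted p = 9.44e-05), by 3.15 for TRDV1 (adjusted p = 0.000699) and by 3.13 for TRAV21/DV12 (adjusted p = 0.000699). For TRDV2-2 a difference was in large part set by its share: at 53.9% of wild-type Tcrd libraries it could rise by at most 0.89 on the log2 scale, against 3.74 in Tcra. For TRDV1 and TRAV21/DV12 that limit was 3.35 and 3.95. The 3 that passed were those called as rising in Tcra from the same values, so this comparison adds no independent evidence. The fit treated Tcra and Tcrd libraries as independent, which the labels do not state.

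The first pattern is the higher share of 5′ J segments in knockout Tcra libraries, a difference of 46.2 percentage points. Coarser resolution of the knockout libraries was expected to shrink it when only pairs at or above the coarsest library's smallest value are used, and it was 55.4 points there. This cut removes the rare pairs of the finer libraries and can itself move the difference, so it cannot decide on resolution. Knockout replicate 1, finer than wild-type replicate 3, had a 5′ J share of 67.7% against 31.1%. A few dominant V–J pairs would remove the difference of 46.2 points when each pair is counted once, and 29.7 points were left. Greater use of V segments that already join 5′ J segments is argued against as the whole cause, since 32 of 33 V segments with a mean of at least 0.5% in both genotypes had a higher 5′ J share of their own in the knockout. The knockout may thus alter J use itself, as a hypothesis, while a difference in thymocyte stages between genotypes was not tested and stays open.

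The second pattern is the resemblance of the Tcra library of knockout replicate 1 to that of wild-type replicate 1. Of 186 3′ J pairs listed only in wild-type replicate 1 among wild-type libraries, 47 were seen in knockout replicate 1, against 7 of 230 listed only in another wild-type library, an odds ratio of 10.8 (Fisher's exact test p = 7.37e-12). Wild-type-like cells in the knockout sample would bring pairs of all wild-type libraries alike, and 3.04% of those of replicates 2 and 3 were seen. Shared V and J preferences are argued against, because within 5 strata of the share expected from V and J totals the odds ratio was 10.1 (permutation p = 0.0001, the smallest that the permutations can give). A candidate explanation is material or reads of wild-type replicate 1 in the library of knockout replicate 1, by a route these data do not show. This was tested in Tcra alone. Spearman's rho over V–J pairs between the replicate 1 libraries of both genotypes was 0.560 in Tcra, above the highest between wild-type libraries (0.525). It was 0.941 in Tcrd, the highest between Tcrd libraries. In Tcrb (0.908) and Tcrg (0.821) it lay below the highest, 0.916 and 0.914. Whether the same candidate applies to the other chains stays open.

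The third pattern is the lower J2 cluster share in knockout Tcrb libraries, a difference of -6.41 percentage points. A few V segments are argued against as its source, since 20 of 22 V segments had a lower J2 share of their own in the knockout, TRBV13-3 and TRBV24 being the exceptions. Altered V use is argued against as the whole cause, because with every library weighted to the mean wild-type V use the difference was -6.09 points. With each V–J pair counted once it was -0.19 points, a measure that is saturated here, as 236 to 240 of the 242 pairs were above 0 in every library. The knockout may act on J choice in this chain, as a hypothesis, and thymocyte stages were not tested here either.

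With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split gave 4 called Tcra V segments, 28 J segments and 72 V–J pairs, and the highest of the other splits gave 0 for each; in 1 of the 10 splits, the real one, was the count as large. For Tcrb J segments the real split gave 6 and the highest other 0, again 1 of 10; the 3 other splits that part all replicate numbers gave at most 0 as well. For Tcrb V segments and V–J pairs the real count and the highest other were 0, so 10 of 10 splits were as large. In Tcrg the real split gave 0 V segments, 0 J segments and 0 pairs, and the highest others were 1, 0 and 1; in Tcrd these were 0, 0 and 0 against 0, 0 and 1, so 10 of 10 splits were as large in each case. For lists, the real split called 2 Tcra J lists, as did the highest other (5 of 10 splits), 3 Tcra V lists, as did the highest other (2 of 10 splits), and 0 Tcrb V lists (10 of 10 splits).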

How the results depend on the processing

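Alternatives added after the data were seen are named in the account of the processing. TMM and DESeq2 scaling, filters on counts, only pairs of at least 10 reads, and thinning to a fixed depth were not run, because the tables hold percentages and counts were not reconstructed. Single values kept their direction in 226 of 244 alternatives, were 0 in 4 (1 of them the Tcra Trav1-Traj33 share over pairs at or above the coarsest value) and reversed in 14, and named segments kept their call and direction in 782 of 969. The cause was not tested unless stated.

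Tcra V segments changed, 4 as reported, were 1 with a smaller pseudocount, 18 with the coarsest library's, 7 without a filter, 10 at a mean of 1% (fewer segments tested), 11 with a variance trend, 15 with the replicate block, 9 with copies summed, and 0 to 15 when a library was left out. Tcra J segments changed (28) were 16 with the smaller pseudocount and 0 to 28 when a library was left out. Tcra V–J pairs changed (72) were 5 with the smaller pseudocount, 140 without a filter (41 higher and 99 lower), 2 at 1% (of 2 tested), 36 after centring, and 7 to 69 when a library was left out. Tcrb V segments changed (0) were 1 at 1%, 2 after centring, 3 with a variance trend, 3 with the replicate block, and 0 to 1 when a library was left out. Tcrb J segments changed (6) were 0 to 8 when a library was left out. Tcrb V–J pairs changed (0) were 2 with a variance trend and 0 to 3 when a library was left out. With an estimated correlation, 1 Tcra J list and 0 Tcra V lists were called. Limma's fry placed the proximal class of Tcra V segments down (adjusted p = 0.346).

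The Tcrg V-J pair entropy difference reversed from 0.0506 to between -0.113 and 0.203 bits when a library was left out and to -0.0721 over pairs at or above the coarsest library's smallest value. The Tcrb Trbv31 share difference reversed from -0.613 to 0.143 points without wild-type replicate 1 (range from -1.21 to 0.143) and to 0.0193 with each pair counted once. Leaving out wild-type replicate 1 alone breaks its pair with knockout replicate 1, and within each replicate number the knockout share was lower. The Tcrg fetal-type V share difference reversed from 0.194 to between -0.216 and 0.827 points when a library was left out and to -0.00942 over pairs at or above the coarsest value. Over those pairs, pairs above 0 differed by 71.7 in Tcra, 0.667 in Tcrb and -2 in Tcrg, since fewer pairs of fine libraries are kept; in Tcrd pairs above 0 the difference ranged from -1.33 to 1.67 when a library was left out. Blocked single values equal the unblocked differences, with an exact sign-flip p of at least 0.25, the smallest it can give.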

Other observations

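The tests in this part were all chosen after the data were seen. Across the 43 Tcra J segments, the log2 fold change followed the J number, with Spearman's rho 0.931 and Pearson's r 0.925 (permutation p = 1e-05, the smallest that the permutations can give), a relation across segments of shared libraries, which are not independent replicates. The knockout effect may therefore follow the place of a J segment along the array.

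The J shift was present within V classes far from the J array. The 5′ J share was 22.2% ± 2.08 in wild type and 69.6% ± 12.8 in the knockout among distal V segments, 20.9% ± 1.07 and 69.2% ± 12.1 among middle ones, and 34.7% ± 2.53 and 76.2% ± 5.93 among proximal ones (n = 3 per genotype, exact permutation p = 0.1 each, adjusted 0.127 over 14 tests). Pairs with a delta V segment joined 5′ J segments in both genotypes, at 85.3% ± 5.90 and 87.0% ± 4.59, a difference of 1.72 points (exact permutation p = 0.8). A shift of the same size in every V class cannot be told apart from a smaller one here, because the wild-type share of this class was already too high to rise by as much.

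If V use followed from the J shift alone, the J-proximal families and delta V segments would hold a like share among 5′ J pairs in both genotypes. They held 15.7% ± 0.326 in wild type and 35.1% ± 0.782 in the knockout, a difference of 19.4 points (exact permutation p = 0.1, adjusted 0.127), so V use may have shifted as well.

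In the Tcrg libraries, the pair of TRGV2 with TRGJ1 held 1.89% in wild-type and 0.899% in knockout replicate 1, and between 8.91% and 17.7% in the other 4 libraries. The lowest of those 4 was 4.72 times the higher of the replicate 1 values. Whether this reflects a difference between replicate numbers cannot be told apart from chance with 1 library per number and genotype. The replicate 1 libraries of both genotypes are also those that resembled each other in Tcra.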
